A study of Danio rerio with 6 samples.

How the data were processed

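Embryos were collected at 72 hours post fertilization and pooled by 50, with 3 pools per group. Per the labels' protocols, messenger RNA was enriched with oligo(dT) beads, fragmented, and made into libraries by a sequencing company. The submitters' processing notes name FastQC 0.12.1, HTSeq 2.0.5 and the genome build GRCz11. The aligner, the annotation release, the strand setting and the handling of multiply mapped reads are not given in the sources used here. Reads that map equally well to paralogs may therefore have been dropped or split, which lowers or blurs the values of near-identical genes, and reads of overlapping antisense genes cannot be told apart.

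The deposited table holds, per the file headers, a raw read count and an FPKM value for each gene and library, with a gene length. The deposited counts are whole numbers with a different total in each library, and no normalization was applied to them. The deposited FPKM values were computed by the authors from these counts: count over gene length and column total gives every value to a largest relative difference of 5.16e-15. The table holds no entries other than genes. Tests used the counts, and the FPKM values served only for that check. Every library column was matched to its sample by name, and coordinates and symbols are those of the table.

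Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM, and the groups were compared with the quasi-likelihood F-test without a replicate block. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and a log2 fold change of at least 1 the added size criterion. SE were taken from the fold change and its F statistic. CPM are counts scaled by the TMM-adjusted totals of the filtered libraries. Library totals ran from 11219706 to 13669995 counts, and the 20 most abundant genes took between 11.6% and 13.6% of them. Mitochondrial genes took between 3.63% and 3.78%. For genes with 0 counts over a group, the fold was bounded by a floor of 3 counts over that group. Bounds cover counting error only, since PCR copies were not distinguished. Libraries of one group differed by more than sampling noise, with chi-square per degree of freedom between 2.63 and 4.03, so no library was counted as a duplicate.

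For gene lists, camera in limma 3.58.1 was run on voom values with a preset inter-gene correlation of 0.01, over 46 lists with at least 5 tested members, adjusted over the lists. The values of 1 of the called lists and of some named genes are not reported here. List members were matched by the table's symbols and, where a symbol was absent, by newer symbols paired with the same gene identifiers. Some of those newer symbols stand for several records or for a record the table names after another protein. After list results had been seen, stricter matching was therefore tried as an alternative. Camera with estimated correlation and fry, which asks whether members move one way without comparing them with other genes, were the other list tests.

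Named genes follow a rule set before the data were examined. It takes wbp11, the 10 largest rises and 10 largest falls among called genes with mean CPM of at least 2, separated groups and a symbol that is not a placeholder, and the 5 most abundant called genes in each direction. For each list described it takes up to 2 called members per direction with the smallest adjusted p, or, in a list with no called member, at most the 2 most abundant as values. Genes outside it are said to have been chosen after their values were seen. The lists and the main design were also set before the data were examined.

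The alternatives set at the same time were RLE and upper-quartile factors, no filter beyond 1 count and a strict filter of CPM 1 in 3 libraries, a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom and the other list tests. Thinned counts, library totals without TMM factors and the stricter list matching were added after seeing the data. The methods were tested on simulated counts with the control-MO means, the library sizes and the within-group spread of these libraries, in a simulated comparison of wbp11-MO with control-MO over 20012 genes. There edgeR recovered 39 of 67 genes changed 1.5-fold, 59 of 67 changed 2-fold and 65 of 66 changed 4-fold, and called 7 of 19772 unchanged genes. Far fewer genes were changed there than were called in the real comparison, so these shares need not hold for it. Camera called the planted list and 0 of the unchanged lists among 46, whose simulated genes varied independently, unlike real ones. Fry and camera with estimated correlation likewise called the planted list and 0 of the others.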

Results

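Gene expression was measured by poly(A)-selected RNA sequencing in whole zebrafish embryos at 72 hours post fertilization. There were 3 libraries from embryos given a control morpholino (control-MO) and 3 from embryos given a morpholino against wbp11 (wbp11-MO), each made from a pool of 50 embryos. A morpholino is an antisense oligomer that blocks either the translation or the splicing of its target RNA. The series title presents loss of wbp11 as a model of VACTERL association, a human pattern of vertebral, anorectal, cardiac, tracheo-esophageal, renal and limb malformations. The count table listed 25432 genes, and 1258 of them had no count in any library. The control-MO libraries held 13521804, 11219706 and 13515170 counted reads, and the libraries labelled wbp11-MO held 13669995, 12805315 and 12772843. Pearson correlations of log CPM lay between 0.985 and 0.988 within groups and between 0.894 and 0.904 across groups. The first principal component separated the groups and carried 83.9% of the variance.

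The targeted gene was examined first. Wbp11 is a nuclear protein that binds the spliceosome. The table held 2 gene records named wbp11, and neither was lower in the libraries labelled wbp11-MO. The record on chromosome 3 (ENSDARG00000101411, 1395079 to 1400309, GRCz11) rose from 14.9 ± 2.61 to 24.7 ± 1.45 CPM (SD, n = 3 each), a log2 fold change of 0.72 ± 0.12 (SE, edgeR adjusted p = 4.7e-06). The record on the unplaced scaffold KN150013.1 (ENSDARG00000099151, 14 to 8486) stood at 8.12 ± 1.02 CPM in the controls and 10.1 ± 0.74 CPM in the other group, a log2 fold change of 0.30 ± 0.16 (SE, edgeR adjusted p = 0.10). With both records summed, the log2 fold change was 0.59 ± 0.10 (SE, edgeR adjusted p = 7.0e-06). Reads can be shared between the records, so the split between them is uncertain. The labels do not say whether the morpholino blocks translation or splicing, and a translation block need not lower the transcript. The transcript level therefore does not check the labels, and directions below refer to the libraries labelled wbp11-MO.

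**Figure D1:**
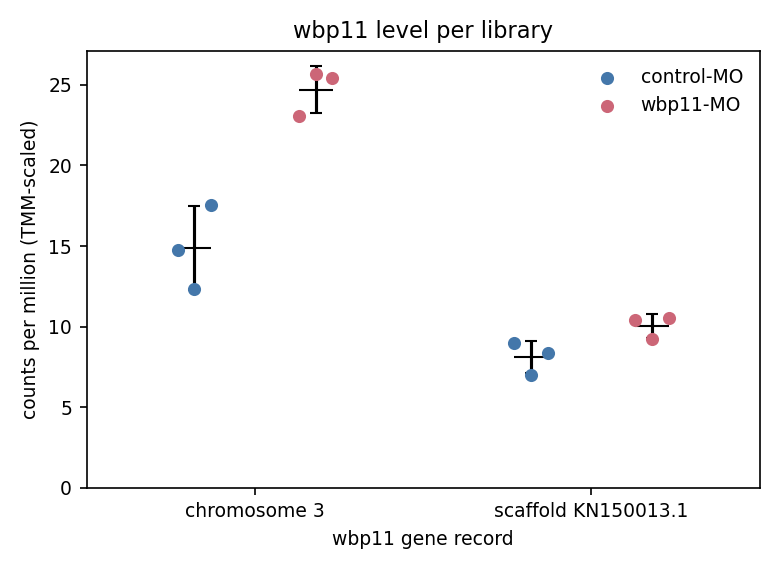
Level of the 2 gene records named wbp11 in CPM (y axis, counts scaled by TMM library size) by record (x axis). Points are single libraries, black dashes are group means and bars are SD (n = 3). The chromosome 3 record averaged 14.9 CPM in control-MO and 24.7 CPM in wbp11-MO.

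The comparison between the groups asked which genes differed in embryos given the wbp11 morpholino. Most measured genes of the photoreceptor, pancreas, intestine and neuron lists fell, and most of the spliceosome, cell cycle, heat shock and cytokine lists rose, by gene-level tests. With an estimated correlation the spliceosome, cell cycle and cytokine lists kept their list-level calls and the others did not (adjusted p = 0.065, 0.19, 0.15, 0.054 and 0.21 with an estimated correlation for photoreceptor, pancreas, intestine, neuron and heat shock genes). The ultraviolet cone opsin gene opn1sw1 (ENSDARG00000045677, chromosome 4, 13577665 to 13580348) fell from 1021 ± 52.2 to 7.95 ± 3.67 CPM, and the spliceosomal GTPase gene eftud2 (ENSDARG00000012261, chromosome 3, 16389020 to 16413635) rose from 78.9 ± 0.79 to 235.2 ± 4.12 CPM (SD, n = 3 each). Of 20012 genes tested, 12349 differed (61.7%), with 6105 higher and 6244 lower in the libraries labelled wbp11-MO (edgeR quasi-likelihood test, adjusted p under 0.05). Among those changed at least 2-fold, falls outnumbered rises, with 2856 genes lower and 1181 higher. The groups did not overlap in 65.4% of tested genes, against the 10% that chance would give for 3 libraries against 3.

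The genes with the largest falls belonged mainly to the exocrine pancreas and to cone photoreceptors. The chymotrypsin-like gene ctrl (chromosome 15, 37820258 to 37829160) had 618 counts over the control-MO libraries and 0 over the others, and was at least 201-fold lower when the floor was set at 3 counts over the group. The gene odam, which encodes a protein of tooth-forming tissue, had 205 counts against 0 and was at least 66.8-fold lower. The chymotrypsinogen gene ctrb1 (chromosome 7, 35075847 to 35079299) fell from 62.5 ± 3.49 to 0.231 ± 0.12 CPM (SD, n = 3). The cone opsin genes opn1sw1, opn1mw1 and opn1sw2 fell from 1021 ± 52.2, 476.5 ± 27.7 and 275.3 ± 21.7 CPM to 7.95 ± 3.67, 2.43 ± 1.43 and 2.46 ± 1.63 CPM. Their log2 fold changes were -6.98, -7.58 and -6.77, with SE of 0.12, 0.12 and 0.14. The trypsin-like gene prss59.2, the lipase gene cel.1, the photoreceptor kinase gene grk1b and scpp5, a gene of mineralizing tissue, completed the 10. The ranks use fitted fold changes, which for ctrl and odam at 0 counts are no bounds, and by its bound odam would stand behind the photoreceptor gene gnb3b, 91.4-fold lower. Without wbp11-MO replicate 1 the log2 fold changes of opn1mw1 and opn1sw2 were -8.20 and -7.37.

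The largest rises included 4 heat shock genes. The gene hsp70l (chromosome 8, 4798158 to 4800911) rose from 10.8 ± 3.29 to 471 ± 152 CPM (SD, n = 3), a log2 fold change of 5.43 ± 0.17 (SE, edgeR adjusted p = 1.4e-22). The genes hsp70.1, hsp70.2 and hsp70.3 rose by log2 fold changes of 5.53, 4.70 and 5.38. They are near-identical copies, so the share of reads given to each is uncertain, as it is for the ms4a17a copies. The leptin gene lepb had 6 counts over the control-MO libraries and 382 over the others, a log2 fold change of 5.94 ± 0.43 (SE). All 6 were in control-MO replicate 2, so without it the control group stood at 0 counts and that fold rests on this library, while without control-MO replicate 1 or 3 it was 5.34. The globin gene hbbe3 rose from 4.41 ± 1.91 to 181.3 ± 18 CPM, while hbbe1.1, chosen after its values were seen, stood at 342.5 ± 55.5 and 358.1 ± 24.4 CPM (edgeR adjusted p = 0.44). Without control-MO replicate 1 hbbe1.1 was called higher (edgeR adjusted p = 0.0055, with 0.0055 to 0.99 over the alternatives), and without control-MO replicate 3 its log2 fold change was -0.0069. The genes acp5a and ctslb (ENSDARG00000074306) rose by log2 fold changes of 5.16 and 5.03, and ms4a17a.3 (ENSDARG00000053563) and ms4a17a.2 rose by 5.70 and 5.61. The ms4a17a genes had 4 counts each over the control-MO libraries, for ms4a17a.2 all in replicate 3, so their folds are uncertain. Without control-MO replicate 1 the log2 fold change of ms4a17a.3 was 6.89, and without control-MO replicate 3 that of ctslb was 5.88.

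The most abundant genes moved by much less. Among the 5 most abundant of the genes that rose, mt-co1, the muscle calcium pump gene atp2a1, myhz1.1 (ENSDARG00000067990), krt4 and mylpfa had log2 fold changes of 0.31, 0.86, 0.28, 0.48 and 0.30. Among the 5 most abundant of those that fell, pvalb2 had a log2 fold change of -0.45 and the cartilage collagen gene col2a1a one of -0.54. The remaining 3, pvalb1, myhz2 and eef2b, had log2 fold changes between -0.12 and -0.10, and leaving out control-MO replicate 1, wbp11-MO replicate 1 or wbp11-MO replicate 2 ended each call. Without control-MO replicate 1 their edgeR adjusted p were 0.19, 0.29 and 0.10, the highest over the alternatives being 0.19, 0.29 and 0.14. The calls of pvalb1 and eef2b were also lost without control-MO replicate 3 (edgeR adjusted p = 0.086 and 0.14), and those of all 3 with a replicate block (edgeR adjusted p = 0.13, 0.10 and 0.058 in the same order). The call of myhz2 was lost with DESeq2 too (adjusted p = 0.055), and that of pvalb1 with thinned counts, chosen after seeing the data (edgeR adjusted p = 0.054).

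**Figure D2:**
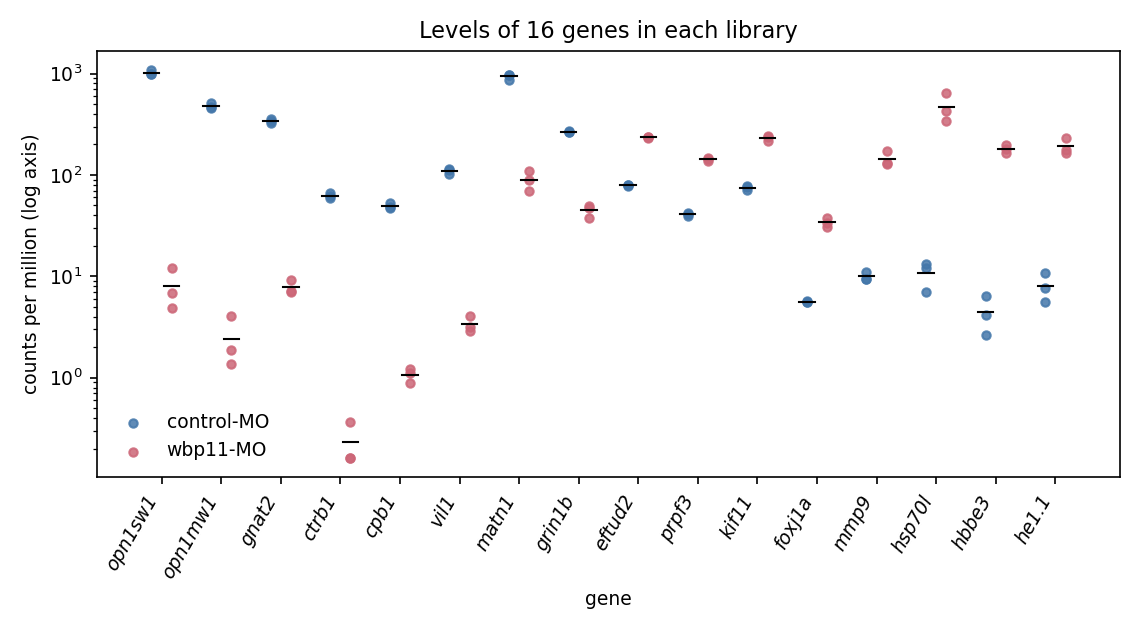
CPM (y axis, log scale) of named genes (x axis) in each library. Points are single libraries and dashes are group means of n = 3. For every gene drawn the groups do not overlap, and opn1sw1 averaged 1021 CPM in control-MO and 7.95 CPM in wbp11-MO.

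Gene lists written before the data were examined were then compared, with counts of members taken from the gene-level test. A competitive test, camera with a preset correlation, called 27 of the 46 lists, 15 higher and 12 lower. With the correlation estimated for each list, 4 lists stayed past the threshold: cell cycle, spliceosome, centriole and centrosome, and the list of complement, chemokine and cytokine genes. The counts of members that rose or fell carry the description below, to be read against 6105 genes higher and 6244 lower among all 20012 tested.

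Of 89 photoreceptor genes tested, 82 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -3.48 (camera adjusted p = 9.1e-29, and adjusted p = 0.065 with an estimated correlation). The cone phototransduction genes gnb3b and gnat2 fell from 342.2 ± 9.26 and 340 ± 18.7 CPM to 3.70 ± 1.13 and 7.82 ± 1.29 CPM (SD, n = 3). The member that rose, the photoreceptor transcription factor gene nr2e3, had a log2 fold change of 0.32 ± 0.14 (SE, edgeR adjusted p = 0.048), and that call was lost without control-MO replicate 1 or 2 and without wbp11-MO replicate 2 or 3 (edgeR adjusted p between 0.13 and 0.18, with 0.023 to 0.18 over the alternatives). It was also lost with a replicate block (edgeR adjusted p = 0.056), the strict filter, DESeq2, limma-voom, upper-quartile factors and library totals without TMM factors, the last of these chosen after seeing the data. Of 61 lens genes, 37 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.1e-04, and adjusted p = 0.54 with an estimated correlation). The crystallin gene crygm2d11 fell from 129.1 ± 25.9 to 14.5 ± 2.22 CPM, and the connexin gene cx23 rose by 0.98 on the log2 scale.

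Of 37 pancreas genes, 27 fell and 4 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -3.80 (camera adjusted p = 2.2e-07, and adjusted p = 0.19 with an estimated correlation). The carboxypeptidase gene cpb1 fell from 49.3 ± 3.3 to 1.07 ± 0.17 CPM (SD, n = 3). The gene nkx6.1, a transcription factor gene of endocrine progenitors, rose from 19.1 ± 0.79 to 29.7 ± 1.08 CPM (SD, n = 3). It is also on the Hedgehog pathway list, and whole embryos do not show which tissue its RNA came from. The median was also -3.80 with the 3 members that had 0 counts in a group set at their bound. By limma-voom the median was -3.92 over all libraries, -2.63 without control-MO replicate 1 and -3.04 without wbp11-MO replicate 3. The expression filter was rerun for each of these, so the members tested can differ, and what moved the median was not tested. Of 55 intestine genes, 38 fell and 6 rose, or 39 and 6 adjusted over the list alone, with a median of -1.16 (camera adjusted p = 1.1e-07, and adjusted p = 0.15 with an estimated correlation). The brush border gene vil1 fell from 109.4 ± 6.15 to 3.38 ± 0.60 CPM. Of 79 liver genes, 45 fell and 18 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0071, and adjusted p = 0.47 with an estimated correlation). The urate oxidase gene uox fell by 4.72 on the log2 scale, and the complement gene cfb rose by 1.57.

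Of 86 neuron genes, 77 fell and 3 rose, or 79 and 3 adjusted over the list alone, with a median of -1.12 (camera adjusted p = 9.1e-29, and adjusted p = 0.054 with an estimated correlation). The glutamate receptor gene grin1b fell from 267.6 ± 3.2 to 44.7 ± 6.1 CPM and the synaptic vesicle gene sypb from 156.1 ± 4.12 to 30.9 ± 2.67 CPM (SD, n = 3), while elavl3, which marks young neurons, rose by 0.24. Of 34 myelin and glia genes, 19 fell and 5 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0045, and adjusted p = 0.11 with an estimated correlation). The myelin gene mbpa had a log2 fold change of -4.33, or -4.97 without wbp11-MO replicate 1, and plp1a rose by 1.63. Neural progenitor genes went both ways, with 40 of 82 higher and 23 lower, or 40 and 24 adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.50 with an estimated correlation). The preset call was lost without control-MO replicate 2 (camera adjusted p = 0.052) and without wbp11-MO replicate 1 (camera adjusted p = 0.072). Over the alternatives the adjusted p of this list ran from 0.0025 by fry, which makes no comparison with other genes, to 0.50 with an estimated correlation. Here notch1a rose by 2.03 and neurod1 fell by 1.31. Of 40 Notch pathway genes, 29 rose and 1 fell, or 30 and 2 adjusted over the list alone (camera adjusted p = 4.6e-09, and adjusted p = 0.12 with an estimated correlation), and lfng, which encodes a glycosyltransferase acting on Notch, rose from 72.5 ± 3.81 to 288.5 ± 9.28 CPM.

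Cartilage and muscle genes divided. Of 76 cartilage and bone genes, 47 fell and 12 rose, or 48 and 12 adjusted over the list alone (camera adjusted p = 4.5e-06, and adjusted p = 0.14 with an estimated correlation). The cartilage matrix genes matn1 and col9a1a fell from 936.2 ± 64.6 and 540.6 ± 18.2 CPM to 89.8 ± 20 and 151.2 ± 15 CPM, while the collagen chaperone gene serpinh1b rose by 1.16 on the log2 scale. Of 97 skeletal muscle genes, 56 rose and 26 fell, or 57 and 26 adjusted over the list alone, with a median of 0.27 and a mean of 0.03 (camera adjusted p = 2.0e-04, and adjusted p = 0.48 with an estimated correlation). The desmin gene desma rose by 1.41 and the troponin gene tnni2a.1 fell by 4.43. Of 85 genes of epidermis and ionocytes, 43 fell and 23 rose, or 44 and 24 adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.54 with an estimated correlation), among them the keratin gene krt1-19d, which fell by 2.76, while krt18a.1 rose by 1.13.

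Of 116 spliceosome genes, 97 rose and 5 fell, or 98 and 5 adjusted over the list alone, with a median log2 fold change of 0.52 (camera adjusted p = 5.2e-19, and adjusted p = 0.042 with an estimated correlation). The gene prpf3 (chromosome 16, 9433738 to 9453591), a component of the U4/U6 particle, rose from 40.9 ± 1.32 to 142.7 ± 5.08 CPM (SD, n = 3), a log2 fold change of 1.80 ± 0.06 (SE, edgeR adjusted p = 3.0e-21). The gene eftud2 rose by 1.58 ± 0.05 on the log2 scale (SE). The splicing factor genes rbm25a and srsf5b fell by 0.82 and 0.38. Of 21 nonsense-mediated decay genes, 15 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.1e-04, and adjusted p = 0.090 with an estimated correlation). Among these the helicase gene upf1 rose by 0.53 and upf3a fell by 1.03. Ribosomal protein genes moved by little, with 68 of 83 higher and 4 lower, the same counts adjusted over the list alone, and a median of 0.21 (camera adjusted p = 1.5e-08, and adjusted p = 0.50 with an estimated correlation).

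Of 68 cell cycle genes, 63 rose and 0 fell, with the same counts adjusted over the list alone, and the median was 0.80 (camera adjusted p = 1.8e-21, and adjusted p = 0.042 with an estimated correlation). The mitotic kinesin gene kif11 rose from 74.8 ± 2.78 to 231.4 ± 12.1 CPM and the cyclin gene ccnb1 from 50.7 ± 1.82 to 131.6 ± 4.79 CPM (SD, n = 3). Of 56 centriole and centrosome genes, 34 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.8e-06, and adjusted p = 0.042 with an estimated correlation). Here aspm rose by 1.36 on the log2 scale, and the centrin genes cetn2 and cetn3 fell from 21.1 ± 2 and 19.8 ± 1.4 CPM to 7.45 ± 0.73 and 14.5 ± 0.43 CPM. The cell cycle inhibitor gene cdkn1a, chosen after its values were seen, had a log2 fold change of 2.04 ± 0.10 (SE). Of 71 motile cilia genes, 38 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.6e-04, and adjusted p = 0.13 with an estimated correlation), and foxj1a, which encodes a regulator of motile cilia, rose by 2.60 while stoml3b had a log2 fold change of -3.52.

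Of 32 heat shock genes, 23 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.9e-08, and adjusted p = 0.21 with an estimated correlation). Of 40 complement, chemokine and cytokine genes, 31 rose and 4 fell, with the same counts adjusted over the list alone, and the median was 1.14 (camera adjusted p = 4.2e-07, and adjusted p = 0.042 with an estimated correlation). The matrix protease gene mmp9 rose from 9.98 ± 0.96 to 143.2 ± 24.8 CPM (SD, n = 3), and the cytokine gene il1b, chosen after its values were seen, from 0.827 ± 0.22 to 14.3 ± 2.68 CPM. Of 25 interferon response genes, 15 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0088, and adjusted p = 0.31 with an estimated correlation). Of 46 erythroid genes, 28 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.33 with an estimated correlation), and the anion exchanger gene slc4a1a rose by 1.92 while the globin gene hbbe2 fell by 0.85. Of 48 myeloid cell genes, 14 rose and 12 fell, or 13 and 12 adjusted over the list alone, and the median of -0.11 differed in sign from the mean of 0.24 and from the test, which pointed higher (camera adjusted p = 0.66). Within that list the neutrophil peroxidase gene mpx fell from 23.8 ± 3.03 to 10.3 ± 1.98 CPM.

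Of 41 circadian clock genes, 30 fell and 2 rose, with the same counts adjusted over the list alone, and the median was -0.86 (camera adjusted p = 3.4e-09, and adjusted p = 0.065 with an estimated correlation). The clock output gene dbpa fell from 37.3 ± 2.89 to 4.53 ± 0.65 CPM. Of 78 oxidative phosphorylation genes, 47 fell and 0 rose, with the same counts adjusted over the list alone, and the median of -0.18 was small (camera adjusted p = 6.8e-05, and adjusted p = 0.47 with an estimated correlation). Of 30 cholesterol synthesis genes, 16 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.47 with an estimated correlation). That preset call was lost without control-MO replicate 1 (camera adjusted p = 0.060) and without wbp11-MO replicate 2 (camera adjusted p = 0.10). Over the alternatives the adjusted p of this list ran from 0.013 by fry, which makes no comparison with other genes, to 0.47 with an estimated correlation.

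**Figure D3:**
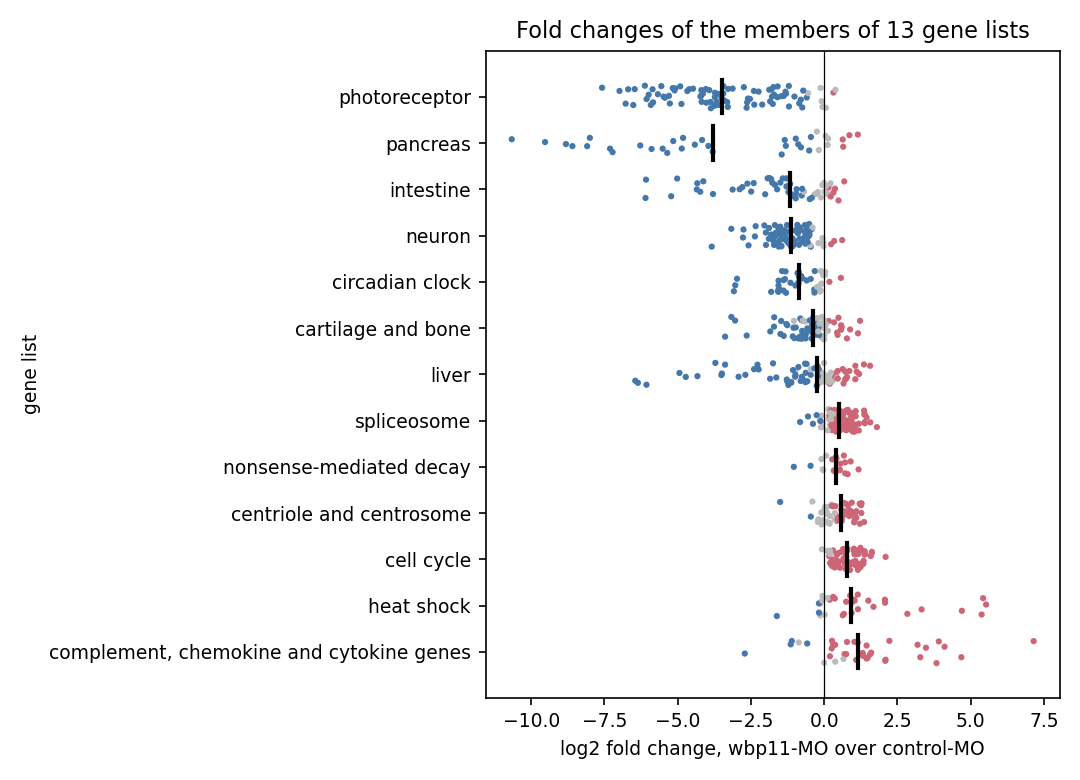
Log2 fold change of wbp11-MO over control-MO (x axis) for each tested member of selected gene lists (y axis). Points are genes, red where they rose, blue where they fell and grey where the edgeR test did not call them, and black bars are list medians; for genes with 0 counts in a group the fitted value is drawn. The photoreceptor median was -3.48 and the cell cycle median 0.80.

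In the lists nearest to the malformations of VACTERL association some genes rose and others fell. The same held for all 20012 tested genes, of which 6105 rose and 6244 fell, so moving both ways is no trait of these lists. Of 71 orthologs of VACTERL and related human disease genes, 25 rose and 17 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.43). In it lfng and eftud2 rose by 1.99 and 1.58 on the log2 scale. The gene zfpm2a, which encodes a cofactor of cardiac GATA factors, fell from 34.9 ± 2.42 to 8.24 ± 1.99 CPM (SD, n = 3), and the collagen gene col11a2 fell by 1.07 on the log2 scale. Of 39 Hedgehog pathway genes, 19 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.32 with an estimated correlation). The signal transducer gene smo rose by 1.59 ± 0.06 on the log2 scale (SE), and the glypican gene gpc3 had a log2 fold change of -2.05 ± 0.33 (SE). Of 54 heart genes, 22 rose and 14 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.32). In the heart list notch1b rose by 1.14 on the log2 scale, and the myosin gene myh7 fell from 145.4 ± 7.11 to 68.6 ± 4.4 CPM. Of 64 pronephros genes, 21 rose and 21 fell, the same counts adjusted over the list alone (camera adjusted p = 0.76). Of 55 genes of the fin bud and posterior Hox list, 18 rose and 11 fell, or 17 and 11 adjusted over the list alone (camera adjusted p = 0.53). There sall4 rose from 22.4 ± 3.31 to 80.4 ± 4.53 CPM and the actinodin gene and2 fell from 540.9 ± 57.8 to 144.4 ± 20.7 CPM. Of 29 notochord and somite genes, 10 rose and 6 fell, the same counts adjusted over the list alone (camera adjusted p = 0.22).

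The remaining lists were not called by camera (adjusted p between 0.061 and 0.83), with counts in brackets for members that rose, then fell. They were the retinoic acid (19 and 7 of 37), Wnt (32 and 18 of 73), BMP (21 and 12 of 48) and FGF pathways (13 and 10 of 45), apoptosis (14 and 7 of 37), hypoxia response (18 and 13 of 36), hatching gland (5 and 3 of 11), endothelium (19 and 12 of 59), Atf4 targets of the amino acid response (19 and 13 of 50), unfolded protein response (13 and 7 of 42), mitochondrial transcripts (2 and 5 of 13), pigment cells (18 and 17 of 46) and glucocorticoid response (9 and 10 of 24). The counts adjusted over the list alone differed for retinoic acid (19 and 8), Wnt (33 and 19), hypoxia (19 and 13), the unfolded protein response (12 and 7) and mitochondrial transcripts (1 and 4), and were the same for the others. The pigment cell list had a median of -0.01 and a mean of -0.12, while the test pointed higher. The retinoic acid list was called without wbp11-MO replicate 3 (camera adjusted p = 0.048), against 0.061 with all libraries. Over the alternatives its adjusted p ran from 0.0016 by fry, which makes no comparison with other genes, to 0.35 by camera with an estimated correlation. The hatching enzyme gene he1.1 (chromosome 22, 14093306 to 14094746) rose from 7.98 ± 2.57 to 191.6 ± 36.3 CPM (SD, n = 3), while cts12 of the same list fell from 7.84 ± 0.65 to 0.23 ± 0.20 CPM (SD, n = 3).

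Genes were counted without a stated strand setting or handling of multiply mapped reads, so values for overlapping genes and close paralogs carry an added uncertainty. The 3 libraries per group are described as biological replicates, and the gene-level p-values are set against the spread between pools of embryos. Camera p-values with the preset correlation compare list members with other genes and do not measure that spread.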

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

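Thinned counts, library totals without TMM factors and the stricter list matching were chosen after seeing the data. The count of changed genes stayed within 1.5 times its main value of 12349 under each alternative run, from 11475 with DESeq2 to 12720 without the filter, and of the genes shared with the main calls 0 changed sign in any of them. Leaving out single libraries gave between 11528 and 11878. With a replicate block 12096 genes were called, 12061 of them shared, and no list call changed. Libraries with the same number did not deviate together, with correlations between -0.04 and 0.01. No pairing by number was seen, but such correlations over all genes cannot exclude one, and the labels state none. The chromosome 3 wbp11 record stayed higher and called in every alternative, and the scaffold record stayed uncalled. The lists depended most on the test. With an estimated correlation 4 lists were called against 27, 4 higher and 0 lower, and 23 single calls were lost. Correlation among members cannot be the whole cause. Calls were lost for lists whose estimate lay below the preset 0.01, as for nonsense-mediated decay (-0.04) and myelin and glia genes (-0.016). Other lost lists had higher estimates, as for photoreceptor genes (0.13). In the simulation genes varied independently. Its planted list had camera adjusted p = 2.9e-35 with the preset correlation and 0.0053 with an estimated one. The estimated setting thus raised adjusted p without any correlation among members. Which part of that setting did so was not tested. With fry, which tests another question, 28 lists were higher against 15. Fry gave the uncalled pigment cell list the direction lower where camera gave higher, with the same median of 0.0113 on voom values (fry adjusted p = 0.15, with 0.15 to 0.90 over the alternatives). Matching by the table's names alone turned the uncalled Atf4 target list (median -0.0329, camera adjusted p = 0.93). That was its highest adjusted p over the alternatives, and the lowest was 0.011 by fry. The stricter matching changed no list call. Over the 202 named genes, calls were lost 49 times, for nr2e3, mt-co2, cry1bb, pvalb1, myhz2, eef2b, zmat3 and cryabb alone. Library totals without TMM factors shifted the median log2 fold change of all genes to -0.07, and 43.2% of called genes were then higher, against 49.4%. The uncalled gene ins, chosen after its values were seen, turned from 0.05 (edgeR adjusted p = 0.85) to -0.17 without control-MO replicate 2, -0.08 without wbp11-MO replicate 1 and -0.0194 with library totals alone, and reached 0.29 without control-MO replicate 3. The uncalled gene hbbe1.1, chosen in the same way, turned from 0.06 to -0.0069 without control-MO replicate 3 and -0.00691 with library totals alone, and was called at 0.20 without control-MO replicate 1. The cause of these turns was not tested. Thinning to the smallest library left 12099 called genes. In the simulation, run at this depth, spread and number of libraries together, edgeR recovered 58.2% of genes changed 1.5-fold. Few simulated genes were changed, against 12349 called among the real ones, so this share need not hold for them.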

Other observations

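The tests of symbol families, of abundant genes, of onset, of early retinal genes and of leukocytes were chosen only after the result was seen, as were their gene sets and the readings of the onset, early retinal and intron tests. Families of genes that share a symbol stem were examined over 315 families with at least 8 tested members. All 16 camk genes, which encode calmodulin-dependent kinases, fell, with a median log2 fold change of -1.51, and 21 of 22 syt genes, which encode synaptotagmins, fell with a median of -1.21. All 8 cplx genes, all 8 gria genes and all 12 grm genes fell. Among genes that rose were 19 of 20 nup genes of the nuclear pore, 24 of 29 polr genes of the RNA polymerases, 18 of 21 kdm genes of histone demethylases and all 8 cct genes of the cytosolic chaperonin. By camera with a preset correlation 62 families were called, 34 higher and 28 lower. With an estimated correlation 0 were, and even the camk genes had an adjusted p of 0.37, so that test decides little about single families. Because the families were examined after the values were seen, the member counts describe these libraries and the families are not shown to stand apart. The kynurenine pathway genes kynu and haao, also chosen after their values were seen, had log2 fold changes of -2.15 and -1.73.

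Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one, the real split itself with 12349, and the highest other count was 0 by edgeR. At an unadjusted p under 0.05 the other splits gave at most 123 genes, and limma-voom called 0. For genes changed at least 2-fold the real count was 4037 and the highest other 0, again 1 split of 10. For gene lists the real count was 27 and the highest other 23, also 1 split of 10, and with an estimated correlation the highest other was 0. Every other split sets 2 libraries of one label and 1 of the other against the reverse, which keeps part of the difference between the labels and widens the spread, so these counts are not those of unchanged libraries. With 10 splits the share cannot go below 0.1.

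Most photoreceptor, pancreas and intestine genes fell. Thinning every library to the smallest total left the photoreceptor median at -3.42 and those of pancreas and intestine at -3.67 and -1.14. Library totals lay so close, from 11219706 to 13669995 counts, that thinning could hardly have moved such medians. The totals themselves argue against depth as the whole cause. A few abundant genes would lower all others alike, yet at library totals without TMM factors the median of all 20012 genes was -0.0705 and the upper quartile of the photoreceptor list was -1.80, which argues against this too. Later onset of late-maturing cells cannot be told apart from loss of exocrine cells: 18 early-onset endocrine pancreas genes, 9 of them also on lists other than pancreas, had a median of -0.07 and 19 late-onset exocrine genes one of -5.36, a difference of 5.29, but all 19 are on the pancreas list whose fall prompted the test. Whether photoreceptor precursors were missing cannot be told apart. The 26 early retinal genes had a median of -0.33, but only 3 of them are on the photoreceptor list while 20 are on other lists such as neural progenitor. A small fall is therefore too weak a test. Of the 26, 12 fell and 9 rose. The genes crx, six7, neurod1 and otx5 had log2 fold changes of -1.38, -1.32, -1.31 and -0.94. Those of nr2e3, prdm1a, prdm1b and atoh7 were 0.32, 0.92, 0.74 and 1.54.

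Most complement, chemokine and cytokine genes, mmp9 among them, rose. The values of 23 leukocyte identity genes, all on the myeloid list, argue against a rise of leukocytes as a whole. Their median was -0.26 (95% bootstrap interval -0.58 to -0.03), below the cytokine median of 1.14. The abundant members arpc1b, rac2, srgn and mpx had log2 fold changes of 0.23, -0.08, 0.22 and -1.21. The 23 were picked, without mmp9 and il1b, after the myeloid list median of -0.11 was known, so this was no independent test. The interval treats the genes as independent. A gain of macrophages alone stays open, since mpeg1.2, irf8 and marco rose by 1.94, 1.09 and 0.62 while mpeg1.1 fell by 0.77. The macrophage gene csf1ra was not called, with a log2 fold change of -0.11 (edgeR adjusted p = 0.53). Of the 23 genes, 4 rose and 6 fell, ptprc among the latter with -1.04. A single library is also argued against, since the lowest of the per-library medians was 1.04 and the highest 1.19. Both groups were given an oligomer. A response of resident cells to the wbp11 oligomer beyond that to the control one, or to damaged tissue, may be the source, and neither was tested.

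Most spliceosome genes rose. A role of incomplete splicing cannot be told apart by intron content: the 394 genes whose span on the genome equals their length, taken as genes without introns, differed from level-matched others by a median of -0.23, but the list has none of them, so the difference does not bear on its rise. Removing the trend on transcript length left the spliceosome median at 0.53, against 0.52 before, which argues against length. Intron reads were not analysed here, so splicing itself was not measured. A compensating rise of splicing genes in response to the wbp11 morpholino is a hypothesis that was not tested, and loss of Wbp11 protein was not measured. More dividing cells could raise the splicing genes too.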
